A study of Scophthalmus maximus with 11 samples.

How the data were processed

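Liver total RNA of 11 juvenile turbot, 5 control and 6 exposed to oil for 14 days, was measured on one-colour (Cy3) Agilent arrays with turbot probes. Per the labels' protocols, 200 ng of total RNA was copied from its poly(A) tail and transcribed into labelled cRNA, and a sample was labelled again as a control; which arrays that concerns is not given in the sources used here. Groups and replicate numbers were taken from the sample labels. They name separate livers, so the spread between samples includes that between fish.

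The deposited scanner files hold intensity values per spot. Per the file headers, they were made with Agilent Feature Extraction 9.5.3.1, which subtracted the background, corrected spatial trends and wrote a processed intensity above 0 for every spot, with surrogate values for spots not above background. Nothing in these files is normalized between arrays. The software's flags per spot (well above background, saturated, outlier) are other values given per the file headers. The authors' deposited table of processed values holds 2715 rows, all 2715 of which matched a probe number of the scanner files; 1 of the 2716 probes is not in it. The authors' deposited values are a score: from the values, the authors had put them on a linear scale and centred them per probe, and how this was done is not given in the sources used here. With probes centred, 11 of 11 columns correlated best with their own array, at a mean Pearson r of 0.948 on the linear and 0.356 on the log2 scale, across probes. The scale factor and the baseline of the centring remain unknown. The column medians were −0.0632, −0.0444, −0.061, −0.0335 and −0.154 for control replicates 3, 4, 5, 7 and 8, and −0.0429, −0.088, −0.0446, −0.122, −0.142 and −0.0582 for oil replicates 1, 3, 4, 5, 6 and 7. This table was used only as an alternative.

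Control spots and spots that the software marked as outliers (1.35% to 3.53% per array) were left out. The log2 of the processed signal was averaged over the spots of a probe, and the 75th percentile over all 2716 probes was subtracted per array. At least 73.4% of the probes were detected on each array, so all probes entered the percentile. A probe was tested when it was well above background, on more than 50% of its spots, on at least 5 arrays, which left 2285 probes and set 431 aside. Saturated spots were kept; there were 8 on all arrays together. Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 9 residual degrees of freedom. A few values per array were compared with exact permutation tests over all 462 splits of the samples. Tables were made with pandas 2.3.3 and figures with matplotlib 3.10.9 in Python 3.11.15.

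The signal over background sets the precision at the low end: negative control spots had a mean signal of 244 to 354 per array, and the spike-in transcripts followed a line with an R squared of 0.997 or more. Where a probe was not well above background on any array of a group, its fold is given as a bound. The limma steps were tested on simulated data for the comparison of oil with control, with 200 of 2285 probes changed and the real means and residual SDs of the probes. They recovered 6% of the probes changed by 0.5 on the log2 scale, 46% of those changed by 1, 84% of those changed by 2 and 100% of those changed by 4. Of the unchanged probes 4 were called, and 0 were called when nothing was changed. The simulation drew independent noise for each probe and holds no sample that stands apart. It also gave a probe the same SD in both groups, whereas the median SD in the data was 0.34 in control and 0.65 in oil.

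Arrays lay on 5 slides, each scanned in its own run. Slide 1 held control 5 and oil 5, slide 2 held control 7 and 8 and oil 6 and 7, slide 3 held oil 1, slide 4 held control 3 and oil 3, and slide 5 held control 4 and oil 4. Slide was therefore fitted as a block, and differences were taken within slides. Because slides 1, 2, 4 and 5 each held as many controls as oil arrays, the block changes the estimates only by dropping oil replicate 1.

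The files give the description of every probe as unknown, and of the probe IDs 0 matched the 26628 genes of the turbot reference table (assembly ASM2237912v1), which holds names and no sequence. Probes therefore carry no gene names here. The planned tests of gene lists and of the CYP1A probe, a usual marker of exposure to oil in fish, were not run. The rule for named features, set before the data were examined, then takes the 2 probes that rose and the 2 that fell with the smallest p. The alternatives also set before the data were examined were quantile normalization, a median shift, normexp background correction (offset 50), no filter and a filter on all 11 arrays, the authors' values, slide and replicate number as fixed or random blocks, array weights, eBayes with a trend and robust prior, a minimum change of 2-fold, and each sample left out. A shift by the spike-in median was chosen after seeing the data, as were the measures of the brightest probes and of the spread between fish. The tests of direction by brightness class and of the agreement between slides were also chosen then.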

Results

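Gene expression was measured in the liver of juvenile turbot (*Scophthalmus maximus*), a flatfish, after 14 days in clean sea water or in sea water carrying a 10% water soluble fraction of fuel oil. This fraction holds what dissolves out of the oil into water. The treatment protocol names heavy fuel oil no. 6 while the title of the series names no. 2, so the grade of the oil is given here only as the sources state it. The fish weighed 358 ± 93 g (SD) and were 28 ± 2 cm long (SD), and each treatment had a tank of its own. The samples analysed here were 5 control livers (replicates 3, 4, 5, 7 and 8) and 6 oil livers (replicates 1, 3, 4, 5, 6 and 7). The design text states 7 turbots in the control tank and 8 in the oil tank; the others were not analysed here. Because all control fish shared a tank and all oil fish shared another, tank and treatment cannot be told apart.

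Each liver was hybridised to 1 one-colour array with 2716 turbot probes, each spotted 5 times. The files describe every probe as unknown and pair no probe with a gene, so probes are reported by their ID. Per array, 1994 to 2303 probes (73.4% to 84.8%) were well above background. The 75th percentile of the processed signal was 5024 ± 597 (SD, n = 5) in the controls and 3958 ± 1091 (SD, n = 6) in the oil arrays. This difference was not past the threshold (log2 difference −0.39, two-sided exact permutation test, p = 0.0887, adjusted p = 0.148 over 5 measures of the arrays). The array labelled oil replicate 5 had the lowest 75th percentile, 2157, against 3392 to 5932 on the other arrays. Its spots of one probe also differed from each other by a median SD of 0.473 on the log2 scale, against 0.0793 to 0.107 elsewhere. The number of arrays limits the precision of all values.

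**Figure D1:**
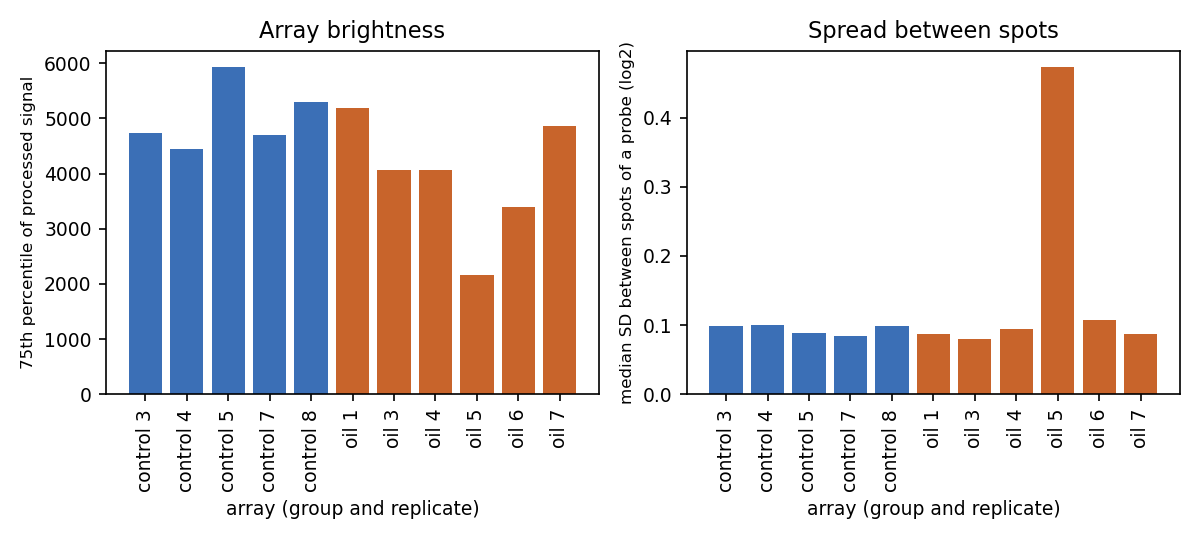
Left, the 75th percentile of the processed signal of each array (linear scanner units). Right, the median SD between the spots of a probe (log2 units). Blue bars are control arrays and orange bars oil arrays. Oil replicate 5 had the lowest 75th percentile (2157) and the widest spread between spots (0.473).

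The comparison of oil with control asks which liver transcripts differed after 14 days of exposure. Of 2285 probes tested, 147 (6.43%) changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, of which 74 were higher and 73 lower in the oil fish. Of these, 136 differed by at least 2-fold, 68 in each direction. The changed probes that were well above background on every array numbered 95. Among them the 47 that rose did so by a median of 1.47 on the log2 scale (quartiles 1.21 and 2.21), and the 48 that fell had a median of −1.34 (quartiles −1.87 and −1.14). The largest rise in this set was 36.8-fold (log2 change 5.20 ± 1.05, SE, limma adjusted p = 0.0422) and the largest fall was 75.1-fold (log2 change −6.23 ± 1.19, SE, limma adjusted p = 0.0395).

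The changes lay close to the threshold: the lowest adjusted p was 0.0322 and 834 probes (36.5%) passed an unadjusted p under 0.05. The count rested on single arrays. Without the array labelled oil replicate 5 it was 988 (432 higher, 556 lower), and all 147 probes were among these. It was 64 without oil replicate 7, 17 without control replicate 8 and 1 without oil replicate 4. Without control replicate 3, 4, 5 or 7, or without oil replicate 1, 3 or 6, limma called 0 probes at the adjusted threshold, with 633 to 771 at an unadjusted p under 0.05. With slide as a fixed block it called 0 (668 unadjusted). The median size of the log2 change of the 147 probes was then 1.72 with a median SE of 0.43, against 1.68 and 0.39 without the block, on 5 in place of 9 residual degrees of freedom. The slides that held both groups held as many controls as oil arrays, so the block gave the same changes as leaving out oil replicate 1, alone on slide 3. Across all tested probes, the difference within a slide correlated with that over the other slides at r = 0.822, 0.871 and 0.843 on slides 2, 4 and 5. On slide 1, which held control replicate 5 and oil replicate 5, r was −0.158. The groups were then permuted within slides in all 48 ways. The mean r of 0.594 was reached by 4 of them, the real grouping and its mirror image included (exact permutation, one-sided, p = 0.0833, where 0.0417 is the smallest these can give). The highest gave 0.679. Under other scalings the rises and falls numbered 97 and 101 with quantile normalization, 85 and 124 with a median shift and 22 and 8 with a spike-in shift. They numbered 168 and 87 with another background correction (normexp), and 2 and 52 on the authors' deposited values, which differ in more than their scaling.

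**Figure D2:**
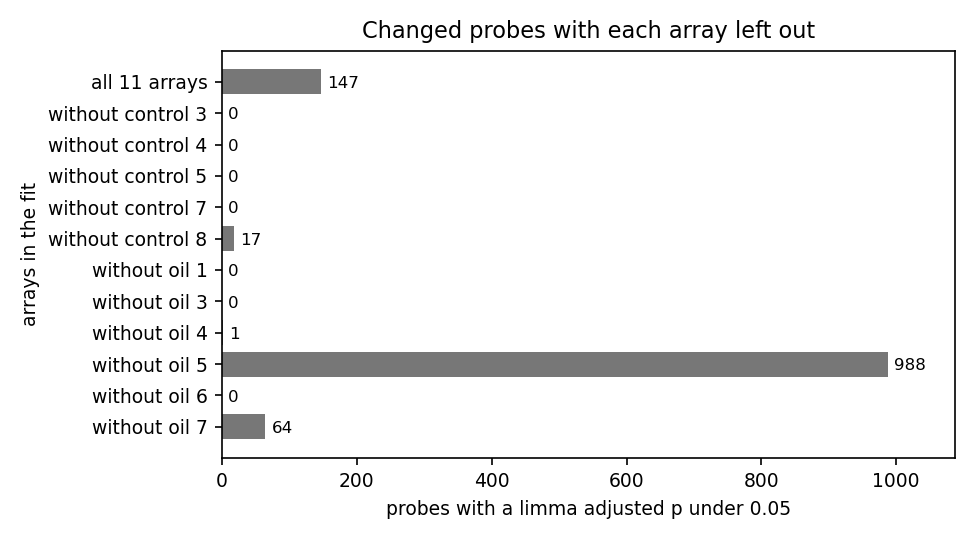
Number of probes with a limma adjusted p under 0.05 with all 11 arrays and with each array left out in turn; bars start at 0. The count was 147 with all arrays, 988 without oil replicate 5, and 0 to 64 without any other array.

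The probes with the smallest p that rose were R1__234 and R1__3040, and those that fell were R1__781 and R1__474. Values are log2 signals relative to the array's 75th percentile. Probe R1__3040 (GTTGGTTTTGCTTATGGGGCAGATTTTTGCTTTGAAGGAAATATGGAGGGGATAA) rose 3.01-fold, from −2.89 ± 0.18 (SD, n = 5) in control to −1.30 ± 0.63 (SD, n = 6) in oil, with a log2 change of 1.59 ± 0.29 (SE) and a limma adjusted p of 0.0351. Probe R1__234 (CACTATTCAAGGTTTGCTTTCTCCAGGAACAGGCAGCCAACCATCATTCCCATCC) was not well above background on any control array and was measured on 5 of the 6 oil arrays. It was at least 2.16-fold higher in oil. This bound sets the mean of the oil group against a control level no lower, on each array, than the dimmest probe well above background. The limma adjusted p was 0.0322, but this p and the later ones of this probe do not test the bound. They belong to the change without a bound, which includes the signals not well above background of the controls and oil replicate 5. Probe R1__781 (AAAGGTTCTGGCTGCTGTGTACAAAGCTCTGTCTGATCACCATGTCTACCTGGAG) fell 4.13-fold, from 4.60 ± 0.15 (SD, n = 5) to 2.56 ± 0.73 (SD, n = 6), with a log2 change of −2.05 ± 0.33 (SE) and a limma adjusted p of 0.0322. Probe R1__474 (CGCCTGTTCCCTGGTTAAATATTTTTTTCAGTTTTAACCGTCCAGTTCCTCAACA) fell 6.57-fold, from 3.73 ± 0.25 (SD, n = 5) to 1.01 ± 1.06 (SD, n = 6), with a log2 change of −2.72 ± 0.45 (SE) and a limma adjusted p of 0.0322. For R1__3040, R1__781 and R1__474, 6 of 6 oil samples lay beyond every control. Such a separation, and a kept sign within slides, is likely for probes chosen by their p on these same arrays.

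In R1__3040, R1__781 and R1__474 the spread between oil fish was wider than that between controls, and oil replicate 5 lay nearest to the controls. Its R1__474 signal was 2.97, where the other oil fish had 0.62 ± 0.50 (SD, n = 5). With slide as a block, the log2 change was 1.56 for R1__3040, −2.06 for R1__781 and −2.65 for R1__474, and the limma adjusted p was 0.113 for these and for R1__234. Within slide 1 the differences were 0.85 for R1__3040, −1.20 for R1__781 and −0.65 for R1__474, and neither array measured R1__234. R1__234 was at least 2.74-fold, 2.37-fold and 1.49-fold higher in oil on slides 2, 4 and 5. On these slides R1__3040 differed by 1.51 to 2.29, R1__781 by −3.16 to −1.72 and R1__474 by −4.15 to −2.51. Without oil replicate 5 the adjusted p was 0.00156 for R1__234, 0.0012 for R1__3040, 0.00137 for R1__781 and 0.000321 for R1__474.

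**Figure D3:**
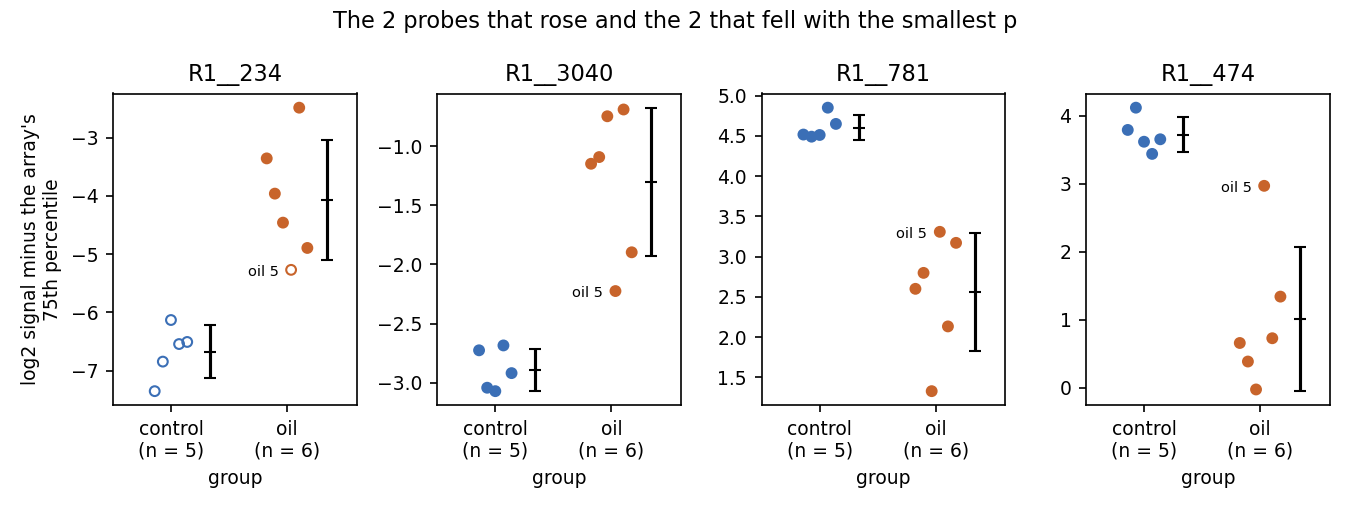
Normalized log2 signal of R1__234, R1__3040, R1__781 and R1__474 in each liver (points; blue control, n = 5; orange oil, n = 6), with the group mean and SD as black bars; open points are arrays where the probe was not well above background. For R1__3040, R1__781 and R1__474 the 6 oil samples lie beyond all controls and oil replicate 5 lies nearest to them. R1__234 was measured on 5 oil arrays and on no control array.

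Of the 1724 probes well above background on every array, the oil group lay wholly above the control group for 50 and wholly below it for 45 (5.51% in all). Chance gives 0.433%, or 7.46 probes, although probes are not independent. Changed probes were found at every brightness. The tested probes were divided into 4 classes of equal size by their mean signal. In the dimmest class (mean signal 80.6 to 509), 27 changed probes rose and 13 fell, against 47 and 60 in the other classes together (odds ratio 2.63, two-sided Fisher's exact test over probes, p = 0.0155, adjusted p = 0.0621 over the 4 classes). Of the changed probes in this class, 3 were well above background on every array, and all 3 rose. In the brightest class (5618 to 430511), 18 rose and 23 fell (Fisher's exact test, p = 0.362, adjusted p = 0.483). Over all 4 classes at once Fisher's exact test gave p = 0.0685, so a difference in direction between classes was not past the threshold, and probes are not independent. Of all 2716 probes, 9 were well above background on no control array and on at least 5 oil arrays. In the other direction, 8 were well above background on all control arrays and on at most 1 oil array. With no exception allowed, 0 were above background on all oil arrays and no control array, and 2 on all control arrays and no oil array. Among the changed probes, 7 were not well above background on any control array, and their oil signal was at least 1.38-fold to at least 16.5-fold higher. A further changed probe was not well above background on any oil array, and was at least 2.39-fold lower there. These counts are not alike, because a probe absent from all controls was tested when at least 5 oil arrays measured it. One absent from all oil arrays was tested only when every control array measured it.

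A larger part of the signal came from a few probes in the oil livers. The 10 brightest probes of an array held 8.21 ± 0.61% (SD, n = 5) of the summed signal in control and 11.2 ± 1.5% (SD, n = 6) in oil (two-sided exact permutation test, p = 0.00433, adjusted p = 0.0216 over 5 measures of the arrays). All 6 oil arrays (8.82% to 12.9%) lay above all 5 controls (7.14% to 8.66%). With slide as a block the difference was 3.09 percentage points, against 2.99 without it (exact permutation within slides, unadjusted p = 0.0417, the smallest these can give). The share was also higher on dimmer arrays. Among the controls its order was the reverse of that of the 75th percentile of the signal, and oil replicate 5, the dimmest array, had the highest share. With the log2 75th percentile as a covariate the difference was 1.97 percentage points (exact permutation, two-sided, unadjusted p = 0.00433). The oil value was higher than the control value on slide 1 (12.9% and 7.14%), slide 2 (10.6% and 8.43%), slide 4 (11.9% and 8.39%) and slide 5 (10.6% and 8.66%). The 10 brightest probes by group mean were shared between the groups for 8 of 10. Relative to the array's 75th percentile, 9 of the 10 brightest in control had a higher mean in oil. Of the 10 brightest by the mean of both group means, 10 did (median log2 change 0.24). That percentile was itself dimmer in oil (log2 difference −0.39), so a rise on this scale need not be a rise of the processed signal. In limma, 0 of these passed the adjusted threshold on their own.

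The oil arrays were more widely spread than the control arrays, mostly through oil replicates 5 and 6, though not past the threshold in the permutation below. Across probes, the log2 profiles of control pairs correlated at r = 0.943 to 0.979, and those of oil pairs at 0.745 to 0.973 (0.833 to 0.973 without oil replicate 5). The root mean square log2 distance of an array to the mean of the others of its group was 0.61 to 0.72 in control. It was 1.51 in oil replicate 5, 1.35 in oil replicate 6 and 0.74 to 0.87 in the other oil arrays. Such distances also hold the spread between spots, which was widest on oil replicate 5. The SD between fish was larger in oil for 82.7% of the probes, with a median SD of 0.65 in oil and 0.34 in control. This share was not past the threshold when group labels were permuted over the 462 splits of the residuals (exact permutation, two-sided, p = 0.0996), and it was 71.3% without oil replicate 5. Each array was also placed on the line from the mean of the other controls (0) to the mean of the other oil arrays (1). The controls lay between −0.17 and 0.24. Oil replicate 5 lay at 0.00952, oil replicate 7 at 0.54, oil replicate 1 at 0.83, oil replicate 4 at 1.41, oil replicate 3 at 1.42 and oil replicate 6 at 1.69. The profile of oil replicate 5 had a mean correlation of 0.954 with the controls and of 0.833 with the other oil arrays.

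**Figure D4:**
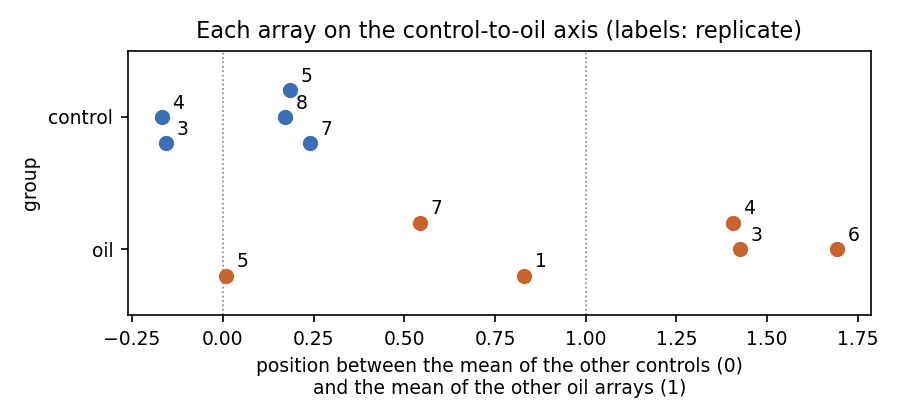
Position of each array between the mean of the other controls (0) and the mean of the other oil arrays (1), over 2285 probes; numbers are replicates. Controls lie between −0.17 and 0.24, oil replicate 5 at 0.00952, and the other oil arrays between 0.54 and 1.69.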

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

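The tests of array noise and of a swap were chosen after the result was seen, as was the comparison of oil replicate 5 with each left-out control over the same probes. Of 24 sets of values examined (12 measures in each group), 2 held a sample far from the others, and chance alone gives about 5% of sets. The first was the spread between spots of a probe in oil replicate 5, a median log2 SD of 0.473 where the other oil arrays had 0.0793 to 0.107. The second was the part of the signal held by the 10 brightest probes in control replicate 5, 7.14% where the other controls had 8.38% to 8.66%.

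The array labelled oil replicate 5 lay among the controls over the whole profile, and the count of changed probes was 147 with it and 988 without it. Noise of this array as the whole reason is argued against by its mean correlation of 0.954 with the controls, which is within the range among controls (0.943 to 0.979) and above that with the other oil arrays (0.833). A swap with a control of this series is argued against too, because the highest control lay at 0.24 on the axis from control to oil, below the lowest of the other oil arrays (0.54). A wrong label, or a swap with a sample from outside the series, is not settled: of the 988 probes called without it, it lay on the oil side of the controls for 44.5%. When oil replicate 5 and each control in turn were both left out of the call (758 to 875 probes called), the left-out control lay on the oil side of the other controls for 34.2% to 73.7%, and oil replicate 5, over the same probes and against the same controls, for 40.5% to 50.3%. Against it, the 10 brightest probes held 12.9% of its signal, above the 7.14% to 8.66% of the controls, although this share also rises on dim arrays and this array is the dimmest. A fish that responded little to the oil was not tested and stays open as well, and the array keeps its label in every comparison.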

How the results depend on the processing

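The fits with the spike-in shift, and the measures of the spread between fish and of the brightest probes with all their alternatives, were chosen after seeing the data. All 147 changed probes had the pooled sign in each alternative that tested them. They were chosen for a clear difference on these same arrays, so a kept sign was likely beforehand and says little. Within slide 1 alone, 113 of the 147 had the pooled sign. The count did depend on the settings. From 147 it moved to 255 with normexp, to 54 on the authors' values, to 1036 with array weights and to 30 with the spike-in shift. It fell to 11 with slide as a random block and to 0 in limma with a fixed block of slide (668 at an unadjusted p under 0.05) or of replicate number (409 unadjusted). In the random block the fitted correlation between arrays of a slide was −0.0892, so these were not more alike than other arrays. Leaving out each sample in turn gave 0 to 988. The remaining 7 alternatives stayed within 1.5 times. The cause was not tested, except that the fixed slide block leaves 5 of 9 residual degrees of freedom. By design, the fixed block of replicate number takes the change only from numbers 3, 4, 5 and 7, which both groups hold. The array weights were 0.178 for oil replicate 5 and 0.259 for oil replicate 6, against 0.99 to 1.92 for the others. The share of rises among the calls was 50.3%, and 49.0% with quantile normalization, 40.7% with a median shift, 73.3% with the spike-in shift, 65.9% with normexp and 3.7% on the authors' values. The median log2 change of all tested probes was −0.07, against 0.04 with quantile normalization and 0.08 with normexp. With the replicate number as a block, 0 probes were called in limma when it was fixed (409 unadjusted) and 147 when it was random. Samples of the same number did not deviate together (r = −0.20, −0.21, −0.19 and −0.31 for numbers 3, 4, 5 and 7, across probes) and none of these controls correlated best with its own number, so the numbers are not read as pairs. Over their alternatives the named probes kept their direction, and passed the threshold in 13 of 23 for R1__234, 13 of 24 for R1__3040, 15 of 24 for R1__781 and 14 of 24 for R1__474 (adjusted p from 0.000321 to 0.275 for the last). The authors' values are not among these alternatives, and the filter on all 11 arrays left out R1__234. The share of probes with the larger SD in oil was 82.8% with quantile normalization (exact permutation p = 0.0368) and 84.3% with a median shift (exact permutation p = 0.0455), which pass the threshold, and 71.3% to 84.5% with each sample left out. Of these, the fits without oil replicate 1 (exact permutation p = 0.0317) and without oil replicate 4 (exact permutation p = 0.0476) pass it, and the others do not. The difference in the part held by the 10 brightest probes was 2.65 to 3.47 percentage points with each sample left out, 3.09 with slide as a block, 1.97 with array brightness as a covariate, 1.65 for the 5 and 6.82 for the 50 brightest. These stayed past 0.05 without adjustment over the 5 measures of the arrays (exact permutation p = 0.0143 without any 1 control and 0.0417 with slide as a block). The gene list and CYP1A alternatives were not run, because the probes carry no gene names. Signal over background limits what can be said of the 431 probes that were not tested.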

Other observations

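Both tests of slide differences and the tests of the jointly varying probes over the oil arrays were chosen after the results were seen, as were these probes themselves. A group of 27 probes varied together between control livers. They were picked on the 5 controls alone, as probes with a control SD of at least 1.5 on the log2 scale that followed the main component of such probes at r above 0.95; 57 probes had an SD that high. In their mean, a probe dimmer than the lowest probe well above background on its array was set to that floor, so low means are upper bounds. The mean was 4.21, 2.99 and 3.18 in control replicates 3, 4 and 8 and −0.73 and −1.17 in control replicates 5 and 7, a range of at least 41.7-fold within the untreated fish. In the oil livers it was −1.15, −3.14, −3.47, 0.80, −4.27 and 0.92 in replicates 1, 3, 4, 5, 6 and 7. On oil replicate 6, 3 of the 27 probes were well above background. The group means were 1.70 ± 2.47 (SD, n = 5) and −1.72 ± 2.24 (SD, n = 6), a difference of −3.42 with these floors (two-sided exact permutation test, p = 0.0433, not adjusted for the search that found these probes). Of the 27 probes 26 had a lower mean in oil, 0 passed limma's adjusted threshold, and 2 were well above background on all 11 arrays.

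A hypothesis for these probes is that the liver pieces held RNA of another cell population in varying amounts. Such a source moves its transcripts together in other livers too. Over the 5 oil arrays other than oil replicate 6, which were not used to choose them, the 19 probes measured on all 5 had a mean correlation of 0.767. Part of this goes with the axis from control to oil, along which 18 of the 19 fell: of 1000 random sets of measured probes of like spread 4 reached this value, and of 1000 of like spread, direction and size of change 45 did (median 0.684). With the position of each array on that axis taken out of every probe, the mean correlation was 0.737, and 0 of 1000 such sets reached it (95th percentile 0.136). Differences between slides are argued against, because control replicates 7 and 8, on one slide, differed by at least 4.35. Genes regulated together in the liver cells themselves may give the same correlation of 0.737 and were not tested, and no cell type can be named without gene names.

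For the 147 changed probes, 100 of the 462 splits of the 11 samples were drawn, the real one included. Of these, 3 called as many probes, and 4 held as many at an unadjusted p under 0.05. Chance as the source of the count is thus argued against by this draw only, for splits that move samples freely across slides. Splits outside the draw were not fitted. The permutations within slides, given below, concern the agreement between slides. The highest of the other splits drawn called 1074. It set oil replicates 1, 3, 4, 6 and 7 against the controls together with oil replicate 5, which points to a structure of the samples: that array sits with the controls. A shift shared by the arrays of a slide is argued against as the source of the changes of the 147 probes. It cancels by design on the slides that held both groups in equal numbers. It enters only because of oil replicate 1, alone on slide 3. With slide as a block, the changes were a median of 101% of the unblocked ones (quartiles 98.1% and 105%). Limma's adjusted threshold was then passed by 0 probes, on fewer residual degrees of freedom. Whether the difference between groups was alike on all slides is not settled. Over all tested probes, the difference within a slide correlated with that over the other slides at a mean r of 0.594. Of 48 permutations of the groups within slides 4 reached it, the real grouping and its mirror image included. Slide 1, which held oil replicate 5, went against the others. Of the 147 probes, 113 had the pooled sign on slide 1 and all 147 on slides 2, 4 and 5. These probes were chosen on the same arrays. The source of the jointly varying probes stays open too: the slope of each changed probe on their mean among the controls predicted a median of 7.25% of its change, but the spread of these probes among the controls allowed a median of at most 32.3%, and probes with a wide spread for their change are seldom called. The tank, which goes with the treatment for all fish, and the treatment itself were not told apart.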
